A study of Homo sapiens with 4 samples.

How the data were processed

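Gene expression was measured in LNCaP, an androgen-responsive human prostate cancer cell line, grown in medium with 10% fetal bovine serum. Per the labels, the cells were transiently transfected by lipofection with a vector expressing MED1, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, or with the empty vector. RNA was taken after 24 hours, and 200 ng of total RNA per sample was turned into biotinylated cRNA for an Affymetrix expression array. There were 4 arrays, 2 per group. Groups were taken from the titles and the transfection label. The free-text description of the empty vector samples names the MED1 vector instead, and was set aside because the title, source name and transfection label all say empty vector.

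The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, per the submitters' processing notes, which give no version. MAS5 summarises the probe pairs of a probe set and scales each array to a common target. In the deposited values the mean after trimming 2% of probe sets at each end was 500.2 on every array, so no further scaling was applied. Other upstream steps are not given in the sources used here. MAS5 signals of weakly expressed genes are noisy, and no detection calls were used, so a low signal has no known background to be set against. Arrays have no read depth, and precision is limited by their number.

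The table held 22277 probe sets, of which 62 Affymetrix controls were left out. Gene names came from the platform annotation: of the other 22215 probe sets, 19064 named 1 gene, 1043 named several and 2108 named none. Entrez identifiers of 19058 probe sets were matched to the RefSeq genes of GRCh38.p14, which was used for names alone. No genome coordinates are given, because the values name no build. No gene was named from a probe set that lists several.

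Signals were transformed to log2(value + 16). Fold changes are on that scale, which understates the change of weakly expressed genes. Probe sets whose mean over the 4 arrays lay under the 40th percentile (a signal of 31) were left out, which removed 8886 and left 13329. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) are those of limma, SDs are between the 2 arrays of a group, and tests are two-sided unless stated. Nothing in the labels says that the duplicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. That spread is mostly borrowed from other probe sets of similar signal. The prior had 7.3 degrees of freedom, against 2 residual ones of each probe set. With 2 arrays against 2, an exact permutation test of a single value cannot reach 0.05. Replicate numbers are shared between the groups, but 2 pairs are too few to treat them as pairing.

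For gene lists, each gene was represented by its tested probe set of highest mean. A set of 33 lists was fixed before the data were examined, and 31 had the minimum of 5 tested genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way. The lists cover Mediator, androgen and estrogen responses, nuclear receptors, cell cycle, stress, immune signalling, metabolism, and markers of other cell types. The genes named in the text were also chosen by a rule fixed before the data were examined: MED1, the 12 passing genes of largest change in each direction, each gene judged by its tested probe set of highest mean alone, the leading members of called lists and of 4 lists of interest, and genes fixed by name, of which 1 is not reported here. Where fewer than 12 genes passed in a direction, others filled the places and are said not to have passed. These were the genes of lowest unadjusted p among those with both MED1 arrays beyond both empty vector arrays. Genes outside this rule are identified as such in the Results, and the additional observations name further ones.

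The procedure was tested on simulated data of 13329 probe sets with 200 changed, in 10 simulations of 2 arrays against 2. It recovered 34.4% of probe sets changed by 1.5-fold, 75.2% at 2-fold, 95.8% at 3-fold and 99.4% at 4-fold, and 6.13% of its calls were unchanged probe sets. The noise was drawn independently for each probe set, with variances from the model fitted to these arrays. The simulated data thus obey the model under test, and these rates need not hold for the real arrays. Alternatives covered the pseudocount (1 and 64), centring on the median, quantile normalization, the filter (none and the 60th percentile), eBayes without the trend or robust, the replicate number as a block, each array left out in turn, 3 other calling rules, averaged probe sets and the estimated correlation. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.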

Results

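The arrays measured steady-state RNA in LNCaP cells 24 hours after transfection with the MED1 vector or the empty vector, with 2 samples in each group. The median signal was 79.0 and 77.4 in the MED1 samples and 80.2 and 83.2 in the empty vector samples. The 3' to 5' signal ratio of the actin controls was 9.40 and 9.32 in the MED1 samples, and 8.14 and 9.45 in the empty vector samples. For the GAPDH controls it was 1.16 to 1.27. Its bearing on probe sets of 1 gene that differ was not tested. Over the 13329 tested probe sets, Pearson's r between arrays was 0.992 for the MED1 pair and 0.990 for the empty vector pair, and 0.986 to 0.991 between arrays of different groups. The first principal component held 46.9% of the variance and placed the MED1 samples at -16.5 and -8.09 and the empty vector samples at 3.28 and 21.3. The series has 1 comparison, MED1 against empty vector, which asks which genes differ in cells given extra MED1.

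The MED1 transcript was higher in the cells given its vector by 1 of its 2 probe sets. The probe set of lower signal read 683 ± 175 in the MED1 samples and 304 ± 16.1 in the empty vector samples (SD, n = 2), a log2 fold change of 1.11 ± 0.16 (SE), or 2.15-fold (limma, Benjamini-Hochberg adjusted p = 0.032). Its individual signals were 559 and 807 with the MED1 vector, and 292 and 315 without. Adjusted over the MED1 probe sets alone, p was 0.000144. The brighter probe set read 1123 ± 69.8 and 1054 ± 60.7 (log2 fold change 0.09 ± 0.10, adjusted p = 0.83), so its difference lay within the spread between replicates. The adjusted p of the dimmer probe set was 0.0608 without empty vector replicate 1, 0.0869 without empty vector replicate 2, 0.381 with no filter on dim probe sets and 0.358 without the variance trend.

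In cells given MED1, 6 of 24 tested type I interferon-stimulated genes rose, and 10 of 26 genes of the response that the transcription factor ATF4 drives when amino acids run short fell. As lists, both passed camera at its preset correlation. Both lost that call when the correlation was estimated (camera adjusted p = 0.284 and adjusted p = 0.486 with an estimated correlation). The estimates were -0.033 for the interferon list and 0.208 for the ATF4 list, so a higher correlation was not the reason for the first. With an estimated correlation, camera has only the 2 residual degrees of freedom of the fit, and 0 of 31 lists passed. IFIT1, which binds foreign RNA, rose from a signal of 19.1 ± 12.5 to 411 ± 33.8 (SD, n = 2). CHAC1, which degrades glutathione, fell from 367 ± 10.0 to 117 ± 27.2. DDIT3, the stress transcription factor CHOP, fell from 1561 ± 3.17 to 549 ± 140. In all, 39 of 13329 probe sets passed (limma, Benjamini-Hochberg), 14 higher and 25 lower in the MED1 samples, and they named 30 genes, 10 higher and 20 lower. At an unadjusted p of 0.05, 1226 passed, where the nominal chance count is 666 and the highest other split of the arrays into pairs gave 821. The count rested on single arrays and settings: it was 94 without MED1 replicate 1, 216 without MED1 replicate 2, 25 without empty vector replicate 2, 0 with no filter on dim probe sets and 5 without the variance trend.

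**Figure D1:**
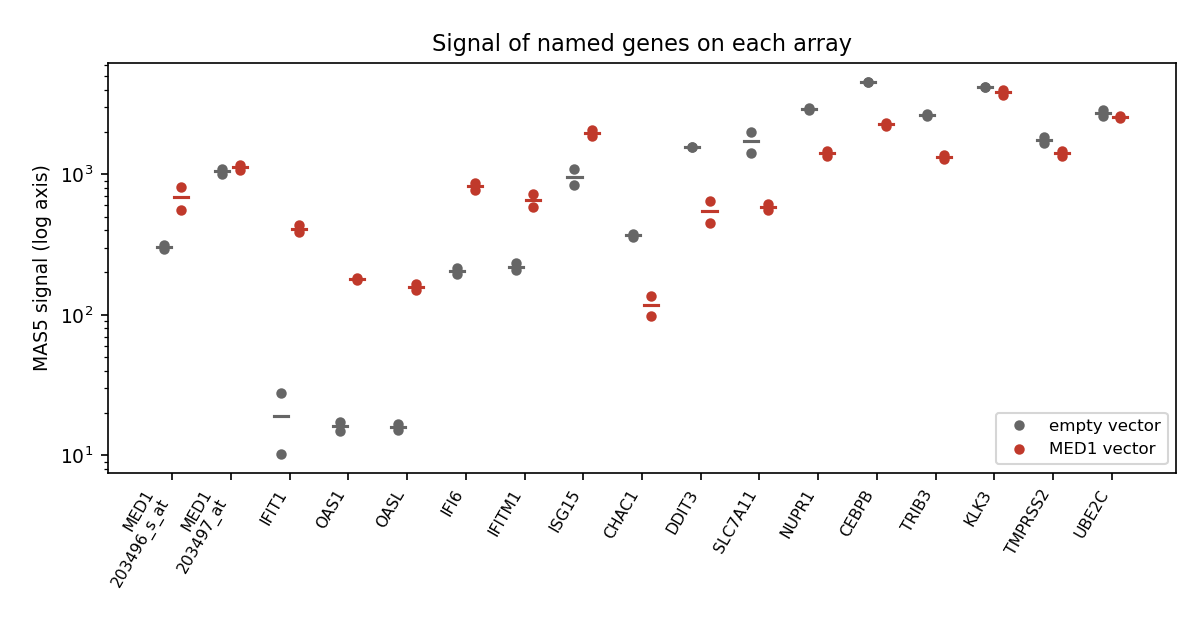
MAS5 signal (log axis) of 16 genes on each array, with points for single arrays, bars for the mean of the 2 arrays of a group, grey for empty vector and red for MED1 vector. IFIT1, OAS1 and OASL lay at means of 19.1, 16.2 and 15.96 with the empty vector and at 411, 179 and 159 with the MED1 vector, while KLK3 read 4187 and 3825.

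The interferon list had 24 tested genes, of which 6 rose and 0 fell over all probe sets tested; adjusted over the list alone, 14 rose and 2 fell. Its median log2 fold change was 0.69, and 21 of the 24 values were positive. With the filter at the 60th percentile, 8 genes were left, with a median of 0.41. IFIT1 rose (log2 fold change 3.65 ± 0.25, adjusted p = 0.000524), as did OAS1, a sensor of double-stranded RNA (2.60 ± 0.21, 0.00149), and its relative OASL (2.45 ± 0.22, 0.00206; limma, Benjamini-Hochberg). Their empty vector signals lay under the filter level of 31, so the sizes depend on the pseudocount: with 1 and 64 in place of 16, they were 4.51 and 2.52 for IFIT1, 3.40 and 1.60 for OAS1, and 3.23 and 1.48 for OASL. IFI6 rose from 205 ± 13.5 to 822 ± 67.4, the membrane-associated antiviral protein IFITM1 from 220 ± 18.4 to 657 ± 95.7, and ISG15, a ubiquitin-like modifier, from 959 ± 177 to 1958 ± 142. A second OAS1 probe set gave 2.03 ± 0.31 and passed, while a second OASL probe set gave 0.53 ± 0.33 and did not. IFIT2 missed the threshold at 1.91 ± 0.32 (adjusted p = 0.0521). MX1, an antiviral GTPase, read -0.71 ± 0.26 (adjusted p = 0.451), at low signals of 22.6 and 47.4, and ISG20, named after its values were seen, read -0.32 ± 0.12; these were the 2 that fell when adjusted over the list alone. The camera test gave an adjusted p of 1.63e-19 over 31 lists, and the adjusted p = 0.284 with an estimated correlation; fry gave 0.0362.

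The ATF4 and amino acid list had 26 tested genes, of which 10 fell and 0 rose over all probe sets tested; adjusted over the list alone, 23 fell. All 26 values were negative, with a median log2 fold change of -0.53. Besides CHAC1 (-1.54 ± 0.17) and DDIT3 (-1.50 ± 0.15), the cystine transporter SLC7A11 fell (-1.50 ± 0.15), with a second probe set at -1.73 ± 0.12 and a dimmer one that did not pass. The stress regulators NUPR1 (-1.05 ± 0.09) and TRIB3 (-0.99 ± 0.09), the transcription factor CEBPB (-1.01 ± 0.09) and the secreted glycoprotein STC2 (-1.001 ± 0.11) each fell to near a level of 0.5 times the control. CARS1, the cytosolic cysteinyl-tRNA synthetase, fell by 0.84 ± 0.12, and adjusted p across these genes was 0.00206 to 0.0219 (limma, Benjamini-Hochberg). ATF4 itself, named outside the rule for named genes, gave -0.53 ± 0.13 and did not pass (adjusted p = 0.238). The camera test gave an adjusted p of 8.28e-33, and the adjusted p = 0.486 with an estimated correlation; fry gave 0.0708.

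**Figure D2:**
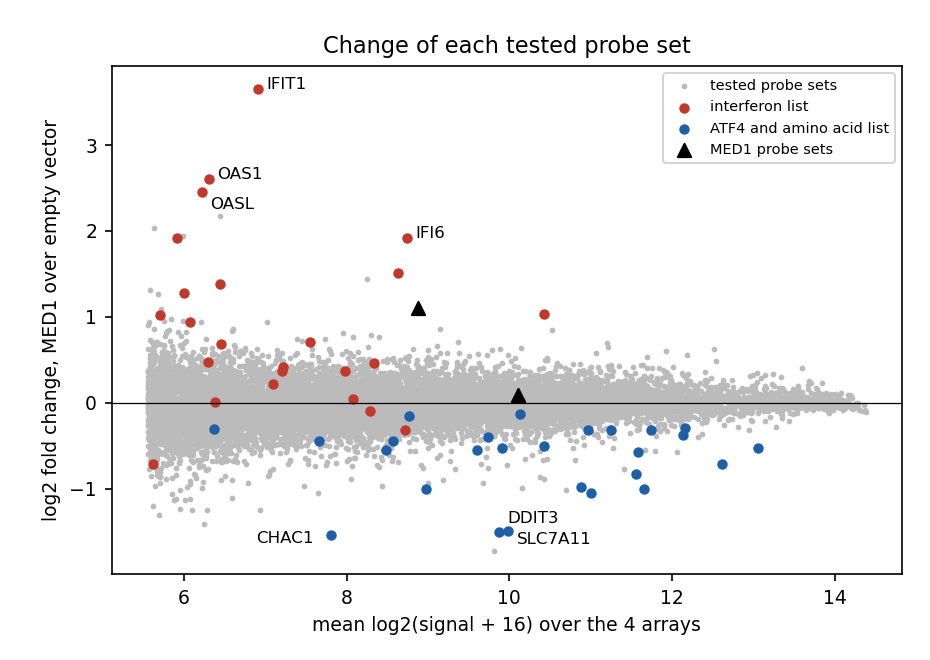
Log2 fold change of MED1 over empty vector (vertical axis) against mean log2(signal + 16) over the 4 arrays (horizontal axis) for the 13329 tested probe sets. The interferon list (red) reaches 3.65 at IFIT1, the 26 ATF4 and amino acid genes (blue) all lie under 0, and the MED1 probe sets (triangles) lie at 1.11 and 0.09.

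The heat shock list had 19 tested genes, of which 0 passed over all probe sets tested; adjusted over the list alone, 3 rose. These were HSPH1 (0.41 ± 0.10), DNAJA1 (0.38 ± 0.09) and CHORDC1 (0.41 ± 0.11), a chaperone of the HSP110 family, an HSP40 and an HSP90 partner. BAG3 gave 0.20 ± 0.10 and DNAJB6 -0.20 ± 0.15. The list median was 0.12 with a camera adjusted p of 0.00405, and the adjusted p = 0.772 with an estimated correlation. It was 0.178 without MED1 replicate 2 and 0.121 without empty vector replicate 1.

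Other passing genes lay outside these lists. TSC22D3, a glucocorticoid- and androgen-induced leucine zipper protein, fell by 1.01 ± 0.11, PMAIP1, the pro-apoptotic protein NOXA, by 0.93 ± 0.11 (a second probe set gave -0.73 ± 0.13 and did not pass), RAD54L, a recombination repair helicase, by 0.90 ± 0.11, and RGS3, a regulator of G protein signalling, by 0.77 ± 0.12. BRIX1, a ribosome biogenesis factor, rose by 0.77 ± 0.12 at the edge of the threshold (limma, Benjamini-Hochberg adjusted p = 0.0495). The pseudogene NACA4P gave 0.84 ± 0.11 (adjusted p = 0.0179), from a probe set of the kind marked as matching other transcripts too. CYP3A4 (1.94 ± 0.32, adjusted p = 0.0521), WDR82 (0.56 ± 0.10, 0.0852) and ELK1 (0.57 ± 0.11, 0.124) filled the places of the rule and did not pass; a second ELK1 probe set gave -0.40 ± 0.21. The CYP3A4 and ELK1 probe sets given here are of the kind marked as matching other transcripts too. On 3 dimmer CYP3A4 probe sets the arrays of the groups overlapped.

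Prostate and mitotic genes fixed by name were also compared. KLK3, which encodes prostate-specific antigen, gave a log2 fold change of -0.13 ± 0.09 (limma, Benjamini-Hochberg adjusted p = 0.702), TMPRSS2 -0.31 ± 0.10 (0.392, and 0.17 ± 0.13 by a second probe set) and FKBP5 0.10 ± 0.15 (0.874). The mitotic genes UBE2C and CDK1 gave -0.09 ± 0.09 (0.812) and 0.22 ± 0.15 (0.689), and 2 other CDK1 probe sets gave 0.01 ± 0.09 and -0.01 ± 0.10. Among 35 tested androgen-induced genes, 1 fell, TSC22D3, and adjusted over the list alone that count was again 1; LRIG1 gave -0.46 ± 0.12 and ZBTB16 -0.33 ± 0.10. The list median was 0.03 (camera adjusted p = 0.678). None of 14 androgen-repressed genes passed, with a median of -0.07 and 9 values negative. As a list they did not pass camera (adjusted p = 0.525) but passed fry (adjusted p = 0.0362), as 1 of 2 lists that did. Of 15 transcription factors and cofactors 0 passed, with a median of -0.02 (0.739), where the median of all tested probe sets was also -0.02; centring each array on its median moved both alike, to 0.03 and 0.04; PIAS2 gave -0.38 ± 0.11 (0.04 ± 0.15 by a second probe set), GRHL2 -0.11 ± 0.10 and CARM1 -0.16 ± 0.14.

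Of 22 other Mediator subunits 0 passed, with a median of 0.05 (camera adjusted p = 0.258); MED7 gave 0.55 ± 0.13 (0.14 ± 0.12 by a second probe set), CDK8 0.24 ± 0.10 and MED17 0.20 ± 0.10. Of 38 genes of G2 and mitosis 0 passed, with a median of -0.08 (0.418); FOXM1 gave -0.22 ± 0.10 and CENPF -0.21 ± 0.11 (0.03 ± 0.20 by a second probe set). MKI67 gave -0.50 ± 0.11 by its brightest probe set and 0.49, -0.12 and 0.12 by 3 others. Adjusted over the list alone, 0 genes passed in either list.

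**Figure D3:**
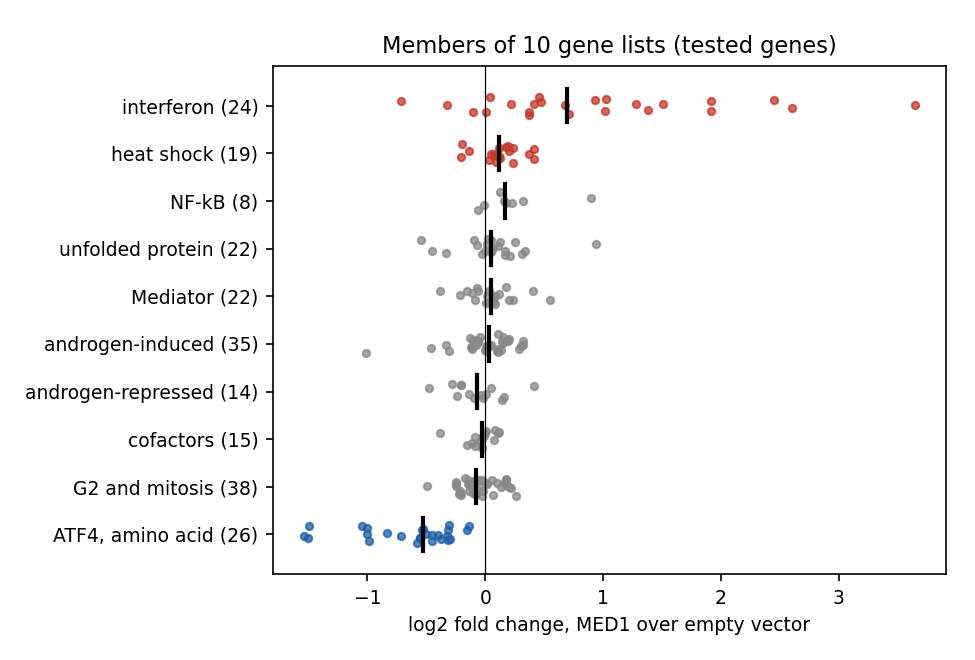
Log2 fold change of MED1 over empty vector (horizontal axis) for the tested genes of 10 lists, 1 point per gene, with a bar at each list's median and the number of genes in brackets. The interferon and ATF4 medians lie at 0.69 and -0.53, and the heat shock median at 0.12; grey lists did not pass the camera test.

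The remaining lists did not pass camera, with adjusted p from 0.0686 for histones (median -0.20) to 0.889 for basal prostate markers (median 0.04). Medians were 0.17 for NF-kappa-B genes, 0.05 for the unfolded protein response, -0.11 for immediate early genes, -0.04 for p53 targets, -0.04 for apoptosis regulators, 0.03 for MYC targets and 0.06 for oxidative and metal stress. They were -0.05 for DNA replication, -0.12 for nuclear receptors, -0.05 for estrogen-induced genes, 0.09 for adhesion and invasion, and -0.06 for growth factor signalling. Metabolic lists gave 0.00428 for cholesterol, 0.03 for fatty acid synthesis, 0.05 for fatty acid oxidation, -0.03 for glycolysis and hypoxia, and 0.01 for the respiratory chain. Ribosomal proteins gave -0.0068 and reference genes -0.000372. Camera and the median differed in sign for fatty acid synthesis and basal prostate (camera down) and for ribosomal proteins and reference genes (camera up). Some of these lists passed camera under other settings. The NF-kappa-B list did so without empty vector replicate 2 (adjusted p = 0.0152), and MYC targets without empty vector replicate 2 (0.0495) and without MED1 replicate 1 (0.0452), all higher. Ribosomal proteins passed higher without MED1 replicate 1 (0.00023) and lower without MED1 replicate 2 (0.0407), and histones passed lower with no filter (0.00978) and with probe sets averaged (0.0205).

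Luminal prostate genes had a median of -0.10 (camera adjusted p = 0.258) and fibroblast genes 0.06 (0.461). The genes named here from short lists, VWF, ENO2 and DDC, fall outside the rule for named genes and were chosen after their values were seen. Of the leukocyte and endothelial genes 1 was tested, VWF at 0.03, and the highest signal among 17 such genes below the filter was 63.4. The neuroendocrine list had 2 tested genes, ENO2 at -0.97 (limma, Benjamini-Hochberg adjusted p = 0.0983) and DDC at -0.28; adjusted over the list alone, both fell. Neither of these lists was tested as a set.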

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

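The tests of dim probe sets, of low signals and of unequal transfection were chosen after the result was seen. Of the interferon list, 14 genes had no probe set above the filter and entered no comparison, yet 13 of their 17 probe sets had both MED1 arrays above both empty vector arrays and 0 had both below. Among all 8886 dim probe sets that share was 13.3%, where chance gives 16.7% (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 7.70e-08 over 14 lists). That p takes probe sets measured on the same 4 arrays as independent, which co-regulated genes are not, so it is too small and serves as a description. IFI27 read 67.5 and 90.7 against 4.62 and 4.52, and IFI44L 42.3 and 38.0 against 13.5 and 7.12. Dim second probe sets of IFI44 and IFIH1, genes measured by brighter ones, were lower instead, at 4.34 and 2.07 against 12.03 and 8.16 for IFI44.

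The rise of the interferon genes did not rest on 1 array: the highest camera adjusted p with any array left out was 1.73e-12. With an estimated correlation the list did not pass (adjusted p = 0.284 with all arrays). Signals near the floor do not account for all of it. The 12 members with an empty vector signal of at least 100 had a median log2 fold change of 0.391, with 10 positive. That median lay above 0.0913, the upper bound of the central 95% of 10000 random lists matched on that signal. Random lists lack the shared variation of co-regulated genes, so that bound is likely too narrow. That test was first run on 13 members chosen by the mean over all 4 arrays, in which the rise itself takes part (median 0.412). The size of the change of genes near the floor, such as IFIT1, stays uncertain. Unequal plasmid DNA or transfection between the vectors cannot be told apart from MED1 itself, because vector and group split the arrays alike; the NF-kappa-B list, which foreign DNA could also raise, had a camera adjusted p of 0.258, which excludes nothing. A response to MED1 and a response to the transfected DNA both stay open.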

How the results depend on the processing

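The count of 39 passing probe sets stayed at 35 to 51 with the other pseudocounts, centring, quantile normalization, the 60th-percentile filter and robust eBayes. It was 0 with no filter on dim probe sets (limma, 0 of 22215), 5 without the variance trend, 73 by a 1.5-fold rule in every array pair, 62 at an adjusted p of 0.1 and 1226 at an unadjusted p of 0.05, the last 2 being looser by construction. With the replicate number as a block it was 239, including all 39, and the block ended no list's call; same-numbered deviations correlated at 0.12 over 2 pairs. Leaving out 1 array gave 25 to 216, with the lone sample assumed to vary like the other group. The log2 fold change of the MED1 probe set that passed was 1.11 with no filter (adjusted p = 0.381) and without the trend (0.358), and 0.85 to 1.37 with an array left out. Of the 20 passing named genes, 0 passed with no filter, 4 without the trend and 15 to 20 with an array left out; none turned direction. Of the other named genes 10 passed with the block, 1 to 7 with an array left out (7 without MED1 replicate 2, MED7 and MKI67 among them) and 0 to 2 with the other settings of the fit. The number of lists passing camera was 3, 0 with an estimated correlation and 2 to 5 with an array left out. Direction turned, without a call, for the list of transcription factors and cofactors (-0.0918 to 0.065 with an array left out), CDK1 (-0.0329 to 0.47) and FKBP5 (-0.036 to 0.242). Beyond looser rules, the cause was not tested. Of the 3 splits of the 4 arrays into pairs, 1 gave as many calls as the real 39, the real one itself, and the highest other gave 0 (821 at an unadjusted p of 0.05); so few splits cannot give a share under 0.05. Without detection calls, changes at low signals have no known background.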

Other observations

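The rule for named genes judged each gene by its brightest probe set; the genes of this paragraph fall outside it and were chosen after their values were seen. The brightest probe set of TXNIP gave -0.56 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0634). The tests of endoplasmic reticulum stress, of the dishes, of the vector transcript, of the tRNA synthetases and, in the form used, of the class I pathway were chosen after the result. By its 2 other probe sets TXNIP, a thioredoxin inhibitor, fell by 0.89 ± 0.09 and 0.87 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 0.0042 and 0.0167). PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, fell by 0.67 ± 0.09, and CEBPG, a partner of ATF4, by 0.65 ± 0.09. CLIC4 fell by 0.76 ± 0.10 and LMO4 by 0.71 ± 0.11. TOX3 fell by 0.64 ± 0.10 by 1 probe set, while its brightest gave -0.36 and did not pass (adjusted p = 0.32). One probe set of IDH3G rose by 2.17 ± 0.21 (limma, Benjamini-Hochberg adjusted p = 0.00243), with signals of 169 against 25.1. Its brighter probe set gave -0.02 (adjusted p = 0.98). The passing probe sets of IDH3G and TOX3 are of the kind marked as matching other transcripts too.

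The fall of the ATF4 genes did not rest on 1 array, with a highest camera adjusted p of 1.12e-21 when any was left out. With an estimated correlation the list did not pass (adjusted p = 0.486 with all arrays), nor with fry (0.0708). The 22 tested unfolded protein response genes did not fall as a set with the ATF4 genes. Their median was 0.0521 (95% bootstrap interval over genes 0.000357 to 0.145), above -0.265, the level of 0.5 times the ATF4 median. Of these genes 16 were positive and 6 negative, and adjusted over the list alone 1 rose and 1 fell. That interval resamples genes on the same 4 arrays, so it leaves out the spread between samples and takes co-regulated genes as independent. Whether endoplasmic reticulum stress took part in the fall of the ATF4 genes is thus not decided. Medium or density of the dishes cannot be told apart from MED1, with 2 samples per group: the list mean differed by at most 0.11 within a group and by -0.65 between groups. Unequal plasmid DNA or transfection between the vectors cannot be told apart from MED1 here either, because vector and group split the arrays alike. MED1, the transfected DNA, the handling of the dishes and a stress change, limited to the ATF4 genes or not, all stay open.

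The 2 MED1 probe sets differed by 1.02 in log2 fold change, and by 0.695 to 1.34 with any array left out, so 1 array was not the cause. The second may lie outside the transcript of the vector, which the probe and vector sequences, not used here, would be needed to test.

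A hypothesis that cytosolic tRNA synthetases outside the list fell with the ATF4 genes was left undecided. The 12 genes had a median of -0.0391 (bootstrap interval -0.257 to 0.11, against -0.265), with YARS1 at -0.52 ± 0.10 and SARS1 at -0.41 ± 0.10, neither of which passed, and with 5 of the 12 positive, up to 0.15 for VARS1. Camera gave an adjusted p of 0.281, and the median differed from that of 9 mitochondrial synthetases by -0.01 (permutation test, p = 0.785). In all 3 criteria were tried, each set after the result; under the last, the interval of the difference from 0.5 times the ATF4 median lay above 0 for 4 of 20 random seeds, so the answer depended on the seed. A further hypothesis was that MHC class I pathway genes outside the interferon list rose as a set to 0.5 times that list's median. The median of these 12 genes did not reach that level, 0.347, at 0.00497 (bootstrap interval over genes -0.0523 to 0.209). The set includes CALR (0.02) and PDIA3 (0.07), which also belong to the unfolded protein response list. Both bootstrap intervals of this paragraph leave out the spread between samples and take co-regulated genes as independent, so they are likely too narrow. Single members lay further out on both sides without passing: ERAP1 (0.45 ± 0.18), PSMB10 (0.25 ± 0.10) and B2M (0.24 ± 0.10) above 0, HLA-G (-0.38) below. The HLA probe sets of this set are of the kind marked as matching other transcripts too. TAP1 (0.37 ± 0.16, not passing) and the dim PSMB9 belong to the interferon list and were left out of the set. Of 3 criteria tried here, the first, camera's adjusted p, was set before that test was run and gave 0.281; a missed threshold shows no absence, so the criterion used was put in its place after the result.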
